A study of Glycine max with 9 samples.

How the data were processed

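Messenger RNA was measured by sequencing in 9 libraries of soybean (Glycine max, cultivar Williams 82) root hair cells, the single-cell outgrowths of the root epidermis. The plants were grown in an aeroponic system, in which roots hang in a nutrient mist, and libraries were made with a TruSeq kit, per the labels' protocols. The titles name the groups 12h, 24h and 48h, with 3 libraries each, and the labels give their ages as 276, 288 and 312 hours after sowing. By these ages the 24h group was 12 hours older than the 12h group, and the 48h group 24 hours older than the 24h group. The ages exceed the hours in the titles by the same amount in all groups, so the titles count from a common point after sowing. What took place at that point is not given in the sources used here. Age and time since that point cannot be told apart. Nothing states that the libraries of a group came from separate plants or growth runs, so p-values measure the spread between these libraries, which may be technical.

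The deposited values are FPKM, fragments scaled by transcript length and by the number of mapped fragments, in 1 table of 56044 gene IDs for all 9 libraries. The name of the deposited table refers to tissue culture, whereas the labels of all 9 samples say root hair cells of aeroponically grown plants. The labels were followed, and the difference was not resolved. TopHat2 2.1.0 and Cufflinks 2.2.1 are named in the submitters' processing notes. The genome build and annotation are not given in the sources used here. Read totals are not part of the values. Where whole reads had been counted, genes under 0.2 FPKM in 2 libraries would share a few fixed ratios, but over the 36 pairs of libraries only 1.48% to 5.94% of such genes lay within 1% of the most common ratio. Whole reads were therefore not recovered, the depth per library is unknown, and no counting intervals are given. A value of exactly 0 in such a table can be a failed estimate, so a gene is described only as listed at 0. Genes with near-identical copies, frequent in the duplicated soybean genome, share reads, and their separate values are uncertain.

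Genes with at least 1 FPKM in at least 3 libraries were tested, 31518 in all. The test was limma's moderated test with an intensity trend (limma 3.58.1, R 4.3.3) on log2(FPKM + 1) over all 9 libraries in 1 fit, with a term per group and a prior of 5.893 degrees of freedom. Fold changes are on that scale, which understates the change of low genes. The 3 pairwise contrasts and an F test over the 3 ages were each adjusted by Benjamini-Hochberg, with calls at an adjusted p under 0.05. Lists of at least 5 tested members were tested with limma's camera at a preset correlation of 0.01. Comparisons of a single value between 2 groups of 3 used two-sided exact permutation tests, whose smallest possible p is 0.1.

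None of the 56044 IDs (0 matched) could be paired with a name in the RefSeq table of assembly Glycine_max_v4.0, and the files do not pair IDs with names. Lists defined by words in gene descriptions, which covered cell walls, hormones, transport, stress and markers of other cell types, could therefore not be tested. The lists that were tested hold loci fixed by ID from published soybean locus names: 4 morning-phased clock loci, 7 evening-phased clock loci, 10 nodulation loci and 7 reference genes. The names of these loci were not checked against any annotation here. The morning-phased list falls below the minimum of 5 members, so its camera test was added after the data were examined. Lists for isoflavonoid synthesis (20 IDs) and for photoperiod and further clock loci (11 IDs, below called the photoperiod list) were added later. They were written after the IDs and the values of the planned lists had been seen, and before the values of their own genes were.

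The design, the lists by ID, the rule for named genes and most of the other settings were chosen before the data were examined. The rule names, per contrast, called genes with a mean of at least 5 FPKM and no overlap between the 2 groups, by the largest fold changes. Because no ID has a description, at most 2 that rose and 2 that fell are printed per contrast. With fewer than 5 called genes it takes the smallest p-values. It also names up to 3 called members of each called list, and the members of the clock, nodulation and reference lists in every contrast.

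The other settings chosen then were pseudocounts of 0.1 and 0.25, no filter, a filter at 5 FPKM, median-of-ratios scaling, quantile normalization, robust variance moderation, a replicate block, fits of only the 6 libraries compared, and leaving out each of the 9 libraries. For lists they were camera with an estimated correlation, camera on ranks, and the rotation test fry. Camera compares a list with the other genes, whereas fry tests a list against no change, so the fry p-values address another question. Array weights and combinations with 12h replicate 2 left out were added after seeing the data, as was scaling for the shares of genes with no overlap.

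The fit was tested on simulated values for the 31518 genes, in which 50 genes per contrast and size were changed by a known amount. At a log2 change of 2, 48% of changed genes were called for 24h against 12h, 32% for 48h against 24h and 38% for 48h against 12h. At a log2 change of 4 these were 88%, 96% and 92%. Each share rests on 50 genes, so differences between the contrasts are not read as differences in power. The real groups differed in spread (median gene SD 0.619 at 12h, 0.365 at 24h and 0.171 at 48h), and genes moved together by library. The simulated noise was drawn independently for each gene and library, with 1 SD per gene for all groups, so it held neither feature. Changed genes were drawn only from those whose mean on the log2 scale corresponded to at least 5 FPKM, so low genes are not covered. The shares therefore do not give the power of the real contrasts.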

Results

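The transcript levels of soybean root hair cells were compared at 276, 288 and 312 hours after sowing, the groups titled 12h, 24h and 48h, with 3 libraries each. The series addresses how transcription changes as root hair cells develop. Between 37256 and 42430 of the 56044 gene IDs were above 0 in a library. Glyma.10G207000 had the highest mean over the 9 libraries. Its values ran from 19625.7 FPKM in 12h replicate 3 to 284074 FPKM in 12h replicate 2, where it made up 19.3% of the FPKM sum.

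The libraries of a group differed most at 12h. Pearson correlations across genes between libraries of 1 group ran from 0.7767 to 0.8831 at 12h, from 0.925 to 0.9513 at 24h and from 0.964 to 0.9694 at 48h. The median SD of a gene on the log2 scale was 0.619 at 12h, 0.365 at 24h and 0.171 at 48h, each over 31518 genes and n = 3. In 12h replicate 2 the 100 highest genes held 53.6% of the FPKM sum, against 28.1% and 24.0% in the other 12h libraries. The first and second principal components held 47.3% and 21.6% of the variance. On the first, 12h replicate 2 (131) and 24h replicates 2 and 3 (53.9 and 93.0) had the highest scores. The scores of 12h replicates 1 and 3 (-49.5 and -70.7) lay near those of the 48h libraries (-66.5 to -42.1). That of 24h replicate 1 was 8.28, so this component did not follow the order of the ages.

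**Figure D1:**
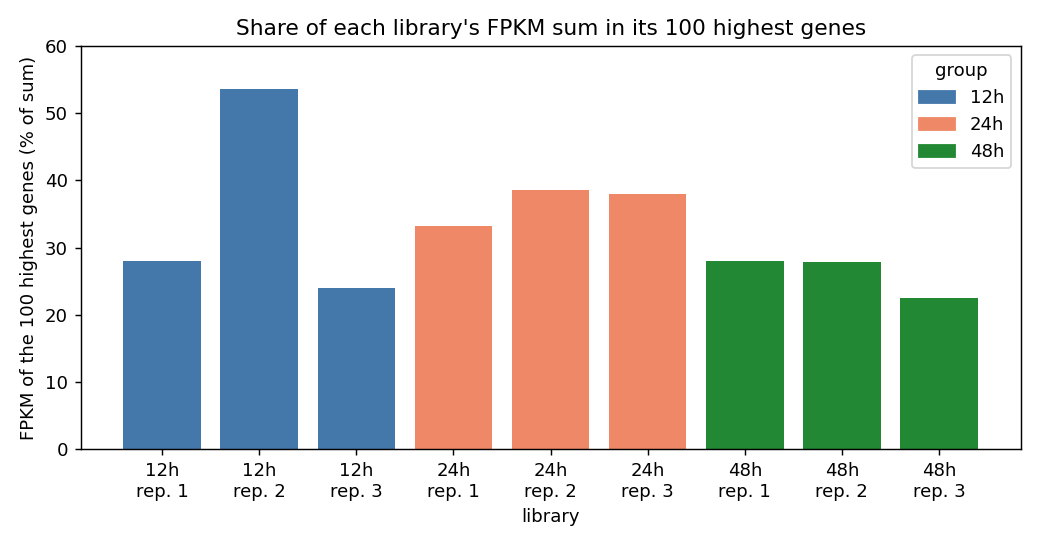
Percent of each library's FPKM sum held by its 100 highest genes, 1 bar per library, coloured by group. The bar of 12h replicate 2 stands at 53.6%, and the other 8 lie between 22.5% and 38.5%.

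Between 12h and 48h, all 4 loci of the morning-phased clock list rose. They are published as soybean genes for LHY, a MYB-type transcription factor of the plant circadian clock that is expressed around dawn. Glyma.16G017400 went from 3.22 ± 0.794 FPKM at 12h to 146 ± 47.0 FPKM at 48h (SD, n = 3 each), a log2 fold change of 5.09 ± 0.563 (SE; limma adjusted p = 0.00899). Glyma.07G048500 went from 1.02 ± 0.416 to 20.9 ± 4.32 FPKM (SD, n = 3 each), with a log2 fold change of 3.44 and a limma adjusted p of 0.0221. Glyma.19G260900 rose by 3.99 on the log2 scale, from 0.122 ± 0.117 to 17.6 ± 6.66 FPKM (SD, n = 3 each), and Glyma.03G261800 by 4.95, with a limma adjusted p of 0.0221 for each. The last was listed at 0.0370, 0 and 0.0692 FPKM in the 12h libraries and at 50.4, 21.3 and 27.7 FPKM in the 48h libraries. These groups lie 36 hours apart by their labelled ages. If all groups were sown at the same hour, which was not checked, they differ in the hour of the day as well as in age. For genes with a daily rhythm the design does not separate hour and age. The same holds for 24h against 12h, 12 hours apart. Every 48h library was above every 12h library at the 4 loci, and 4 of 4 passed when adjusted over the list alone.

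The 7 loci of the evening-phased clock list went the other way as a list in this contrast. Their mean log2 fold change was -0.72, 5 of 7 were lower at 48h, and the list was called down by camera (adjusted p = 3.78e-06). The call was lost with an estimated correlation (adjusted p = 0.391). Against no change, which is another question than camera's, fry gave an adjusted p of 0.353. The size rested on single 12h libraries, with a mean of -0.43, -1.24 and -0.47 without 12h replicates 1, 2 and 3. All 7 were lower at 48h without 12h replicate 2, after median-of-ratios scaling and after quantile normalization. With all libraries, 0 of 7 members passed, both over all genes and adjusted over the list alone. Glyma.04G050200, published as soybean ELF3, a repressor in the evening complex of the clock, had 28.3 ± 19.6 FPKM at 12h and 7.29 ± 1.87 FPKM at 48h (SD, n = 3 each; limma adjusted p = 0.458). Glyma.11G136600 and Glyma.12G060200, published as genes for LUX, another member of that complex, had 5.96 ± 2.04 and 2.21 ± 0.702 FPKM at 12h, against 1.94 ± 0.230 and 0.467 ± 0.106 FPKM at 48h (SD, n = 3 each). Glyma.10G221500, published as a GIGANTEA gene, had 17.5 ± 15.1 FPKM at 12h and 12.1 ± 5.004 FPKM at 48h (SD, n = 3 each), with a fitted log2 fold change of 0.051 that did not pass. The other member with a positive value was Glyma.04G166300, with 6.85 ± 3.70 and 7.13 ± 0.883 FPKM (SD, n = 3 each) and a log2 fold change of 0.16. Both values turned negative without 12h replicate 2 and after either scaling, and that of Glyma.10G221500 also without 48h replicate 2. Glyma.20G170000 had a log2 fold change of -1.04. Glyma.06G196200 had 12.0 ± 4.35 FPKM at 12h and 8.73 ± 1.85 FPKM at 48h (SD, n = 3 each). The camera call of the morning-phased list in this contrast (adjusted p = 8.35e-12) was lost with an estimated correlation (adjusted p = 0.0646). Against no change, fry gave an adjusted p of 0.00407.

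**Figure D2:**
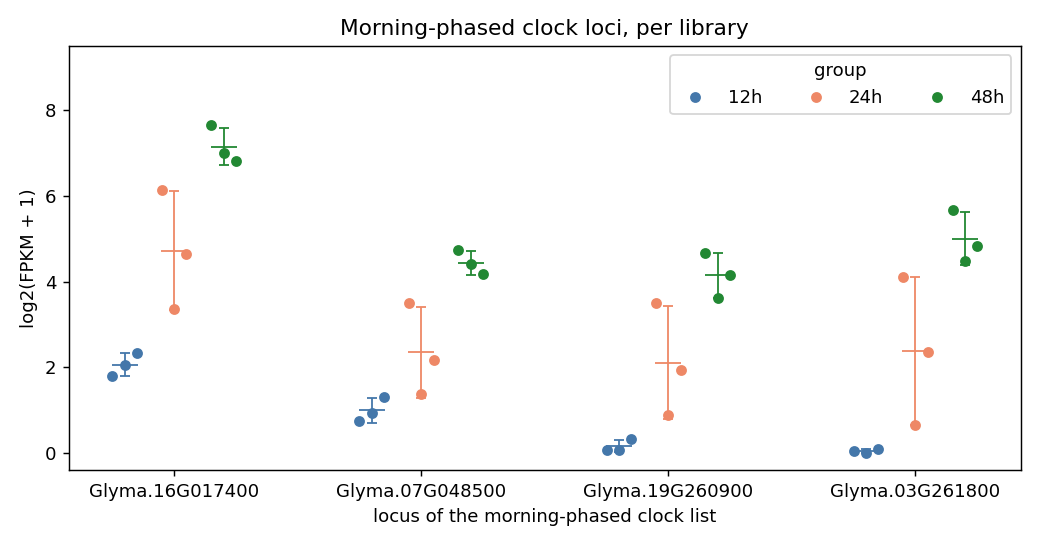
Levels of the 4 morning-phased clock loci on the log2(FPKM + 1) scale, 1 point per library, with the mean and SD of each group (n = 3) as a bar and whiskers. All 48h points of a locus lie above its 24h and 12h points, and Glyma.16G017400 has a mean of 3.22 FPKM at 12h and 146 FPKM at 48h.

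Of all tested genes, 37 rose and 0 fell from 12h to 48h (limma, adjusted p under 0.05; 3412 at an unadjusted p under 0.05). Besides the clock loci, Glyma.08G122200 rose from 0.824 ± 0.362 to 74.9 ± 15.0 FPKM (SD, n = 3 each; log2 fold change 5.38 ± 0.383 SE, limma adjusted p = 0.000287). Glyma.11G158200 rose by 4.96 on the log2 scale (limma adjusted p = 0.0267), from 0.0425, 0 and 0.660 FPKM in the 12h libraries to 53.6, 28.5 and 31.2 FPKM in the 48h libraries. The first passed in 23 of 23 alternative fits and the second in 13 of 23, with adjusted p-values up to 0.173. The median log2 fold change of all tested genes was 0.341 as deposited and -0.0225 after median-of-ratios scaling, under which 1 gene rose and 0 fell, and quantile normalization gave 6 that rose and 1 that fell. The count was 2 without 12h replicate 1, 1 without 12h replicate 2, 58 and 12 without 24h replicates 1 and 3, and 1, 4 and 7 without 48h replicates 1, 2 and 3. Adjusted p-values of the clock loci passed 0.05 in 17, 13, 13 and 13 of 23 alternative fits, with the sign kept in 23 of 23 and adjusted p-values up to 0.16. Of the 4 loci, 0 passed after median-of-ratios scaling, with no filter, or without 12h replicate 1, 12h replicate 2 or 48h replicate 1. Without 24h replicate 3, 48h replicate 2 or 48h replicate 3, 1 passed. All 4 passed in the fit of only the 12h and 48h libraries. They also passed there with median-of-ratios scaling, a combination chosen after seeing the data (limma adjusted p 0.0158 to 0.0302). With scaling and 12h replicate 2 left out, also chosen then, 0 passed (limma adjusted p 0.114 to 0.16). Their log2 fold changes with all libraries were 3.05 to 4.68 after scaling.

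Between 12h and 24h, 10 genes rose and 2 fell (limma, adjusted p under 0.05; 3140 at an unadjusted p under 0.05). Glyma.11G236700 rose from 2.27 ± 0.813 to 92.9 ± 30.1 FPKM (SD, n = 3 each; log2 fold change 4.82 ± 0.390 SE, limma adjusted p = 6e-04), and Glyma.08G122200 from 0.824 ± 0.362 to 52.2 ± 27.8 FPKM (SD, n = 3 each; log2 fold change 4.76, limma adjusted p = 6e-04). Both passed in 23 of 23 alternative fits. The 2 that fell were listed at 0 in all 24h libraries. Glyma.10G003900 had 28.6, 54.4 and 72.9 FPKM in the 12h libraries (limma adjusted p = 0.00583), and Glyma.08G263400 had 8.74, 9.17 and 17.7 FPKM (limma adjusted p = 0.0121). They passed in 19 and 17 of 23 alternative fits, with adjusted p-values up to 0.149 and 0.151. Only these 2 genes were listed at 0 in all 24h libraries and at 1 FPKM or more in the other 6, and 10 of the 84 choices of 3 libraries gave at least as many such genes, up to 23.

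With all libraries, none of the clock loci passed the test over all genes from 12h to 24h (evening-phased adjusted p 0.499 to 0.979), whereas 4 of the 4 morning-phased loci passed when adjusted over the list alone. Glyma.16G017400 had 34.4 ± 31.5 FPKM at 24h (SD, n = 3), with 69.8, 9.33 and 24.1 FPKM in its libraries (limma adjusted p = 0.326 against 12h). It passed without 12h replicate 2 (adjusted p = 0.037) and without 24h replicate 2 (adjusted p = 0.043). Without 12h replicate 2 the evening-phased Glyma.06G196200 and Glyma.04G050200 also passed, both lower at 24h (adjusted p = 0.0325 and 0.0288). As deposited, the lowest 24h library was still above the highest 12h library at each of the 4 morning-phased loci. After median-of-ratios scaling, 12h replicate 2 lay below every 24h library at 3 of them, so the groups overlapped at the other. Camera called the morning-phased list up (adjusted p = 3.99e-05; adjusted p = 0.169 with an estimated correlation) and the evening-phased list down, with 7 of 7 members lower at 24h and 6 of 7 without 12h replicate 1, 12h replicate 3 or 24h replicate 3 (adjusted p = 0.00333; adjusted p = 0.572 with an estimated correlation). Median-of-ratios scaling left 5 genes, 3 that rose and 2 that fell, and quantile normalization left 2, both higher at 24h. Without 12h replicate 2 the count was 3803, of which 1382 rose and 2421 fell, and without 12h replicate 1 it was 4. It was 3, 22 and 2 without 24h replicates 1, 2 and 3, and 7, 6 and 7 without 48h replicates 1, 2 and 3. Camera did not call the evening-phased list in this contrast without 24h replicate 1 (adjusted p = 0.0625).

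Between 24h and 48h, no gene passed (0 with limma at an adjusted p under 0.05; 5631 at an unadjusted p under 0.05). The smallest p-values belonged to the pair of genes listed at 0 in all 24h libraries, Glyma.10G003900 (limma adjusted p = 0.0858) and Glyma.08G263400 (limma adjusted p = 0.129), which had 44.5, 52.9 and 8.48 FPKM and 12.6, 3.81 and 8.06 FPKM in the 48h libraries. The morning-phased loci had log2 fold changes of 2.43, 2.09, 2.04 and 2.63 and a limma adjusted p of 0.248 each, and 4 of 4 passed when adjusted over the list alone. All 4 passed over all genes in the fit of only the 24h and 48h libraries (adjusted p 0.0303 to 0.0453) and without 12h replicate 2 (adjusted p 0.0372 to 0.0481). With median-of-ratios scaling added to these fits, after seeing the data, 1 of 4 passed in the first (adjusted p 0.0453 to 0.0721) and 0 of 4 in the second (adjusted p 0.0577 to 0.0784). Their list was called up by camera (adjusted p = 0.000119; adjusted p = 0.169 with an estimated correlation). The evening-phased list was not called (adjusted p = 0.308), and its members had adjusted p-values of 0.389 to 0.977.

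The count of 0 depends on which libraries estimate the spread. A fit of the 24h and 48h libraries alone, without the more variable 12h group, called 5412 genes, 4314 higher and 1098 lower at 48h. After median-of-ratios scaling, a combination chosen after seeing the data, that fit called 3809, with 1936 higher and 1873 lower. With all groups but without 12h replicate 2 the count was 3730, with 3146 higher and 584 lower, and 0 when scaling was added. At an unadjusted p under 0.05 (limma), that fit had 10362 genes before scaling and 10139 after it. The fall to 0 is therefore one of adjusted p-values crossing the threshold, not a loss of most low unadjusted p-values. The adjusted count was 1 without 12h replicate 1 and 3 without 48h replicate 3. Of the 31518 genes, 13971 (44.3%) showed no overlap between the 24h and 48h libraries, 10290 of them higher at 48h. For a single gene chance gives 10%. Genes move together by library, so the share in a single split can lie far from 10% without an effect of age. Shares for other splits were not computed, so how unusual 44.3% is was not tested. The median log2 fold change of all tested genes was 0.228 as deposited and -0.0154 after median-of-ratios scaling. After that scaling, chosen here after seeing the data, 14251 genes (45.2%) showed no overlap, 7086 higher and 7165 lower. The share was 10.3% for 24h against 12h and 22.0% for 48h against 12h as deposited, and 14.5% and 15.8% after scaling.

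**Figure D3:**
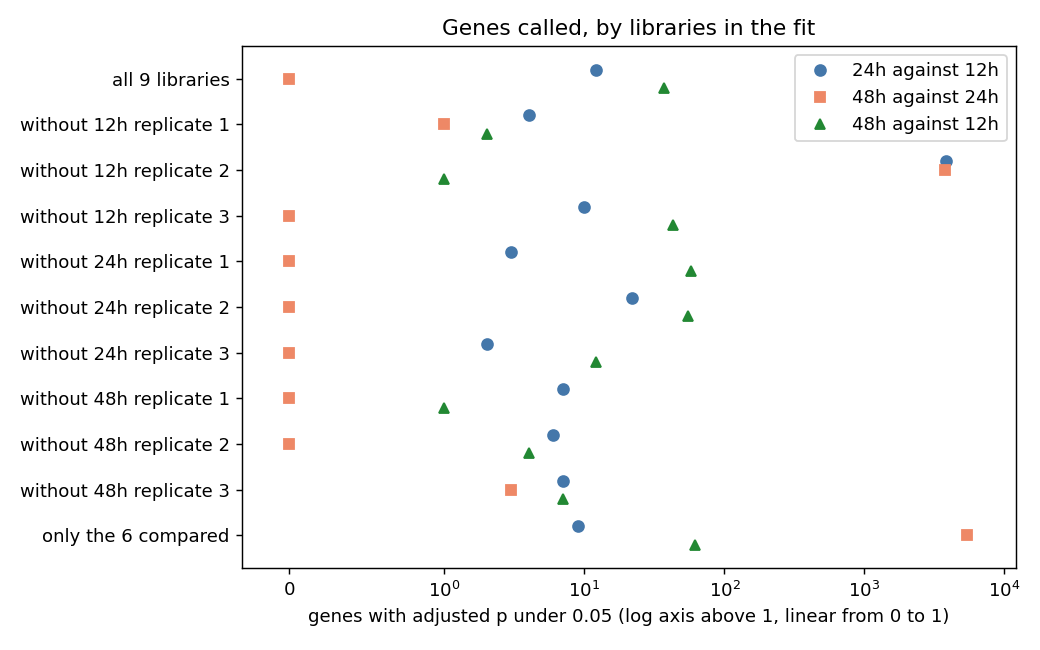
Number of genes with a limma adjusted p under 0.05 in each pairwise contrast (horizontal axis, logarithmic above 1 and linear from 0 to 1), for the fit of all 9 libraries, for fits without each library, and for fits of only the 6 libraries compared. The counts for 24h against 12h and 48h against 24h reach 3803 and 3730 without 12h replicate 2, and 48h against 24h reaches 5412 with only the 6 libraries compared.

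Over the 3 ages together, 9 genes changed by limma's F test (4277 at an unadjusted p under 0.05), against 3123 without 12h replicate 2. The count was 4 and 17 without 12h replicates 1 and 3, 37, 44 and 2 without 24h replicates 1, 2 and 3, and 5 each without 48h replicates 1 and 2. As a summary of the clock lists, the mean log2 level of the morning-phased loci minus that of the evening-phased loci was -2.29 ± 0.891 at 12h, 0.480 ± 1.91 at 24h and 2.79 ± 0.488 at 48h (SD, n = 3 each). The exact permutation p was 0.2 for 24h against 12h and 0.1 for both contrasts with 48h, the smallest that 3 against 3 libraries can give.

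Of the 10 nodulation loci, 4 published as leghemoglobin genes, the oxygen-binding proteins of nodules, were listed at 0 in all 9 libraries (Glyma.10G199000, Glyma.20G191200, Glyma.10G198800 and Glyma.10G199100). Glyma.04G000600, Glyma.02G311000 and Glyma.06G000400 were under the filter, and 3 were tested, of which 0 passed in any contrast. Among these, Glyma.14G001600 had 0.578 ± 0.560, 1.475 ± 0.888 and 0.586 ± 0.135 FPKM, Glyma.02G270800 had 16.1 ± 5.88, 18.3 ± 6.28 and 25.97 ± 4.89 FPKM and Glyma.11G063100 had 19.995 ± 11.5, 22.5 ± 9.35 and 27.7 ± 5.12 FPKM at 12h, 24h and 48h (SD, n = 3 each). Of the 7 reference genes, 0 passed over all genes, and 1 passed for 24h against 12h when adjusted over the list alone (0 for the other contrasts). That was Glyma.20G141600, with 259 ± 28.0 FPKM at 12h, 642 ± 123 FPKM at 24h and 423 ± 32.6 FPKM at 48h (SD, n = 3 each). Mean levels at 12h, 24h and 48h were 45.6, 47.5 and 61.0 FPKM for Glyma.12G020500, 60.02, 63.8 and 97.3 FPKM for Glyma.12G051100, and 18.2, 8.46 and 24.7 FPKM for Glyma.03G137100, whose adjusted p over the list alone was 0.0512 for 48h against 24h (limma). They were 128, 196 and 145 FPKM for Glyma.18G290800, 131, 231 and 148 FPKM for Glyma.02G276600, and 1112, 1665 and 1146 FPKM for Glyma.17G186600. With all libraries camera did not call the reference list in any contrast (adjusted p = 0.103, 0.286 and 0.308). Without 12h replicate 1 it was called up for 24h against 12h (adjusted p = 0.044).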

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

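Array weights and the combined settings were chosen after seeing the data; the other settings were planned. Depth is unknown, so its part in these changes was not tested. In the order 3 ages, 24h against 12h, 48h against 24h and 48h against 12h, all 9 libraries gave 9, 12, 0 and 37 genes. Leaving out 1 library gave 2 to 3123 genes over the 3 ages, 2 to 3803 for 24h against 12h, 0 to 3730 for 48h against 24h and 1 to 58 for 48h against 12h, and 1 to 3 camera calls of the evening-phased and reference lists over the 3 contrasts. The highest of the first 3 ranges are without 12h replicate 2, and 58 is without 24h replicate 1. A pseudocount of 0.1 or 0.25 gave 35 genes over the 3 ages and 2 for 48h against 24h. No filter gave 3, 2, 1 and 2. The filter at 5 FPKM gave 22 for 48h against 12h. Median-of-ratios scaling gave 2, 5 and 1 and quantile normalization 2, 2 and 7, each with 0 for 48h against 24h. Robust moderation gave 44 over the 3 ages, 1 for 48h against 24h and 66 for 48h against 12h. Only the 6 libraries compared gave 5412 for 48h against 24h and 62 for 48h against 12h. Array weights gave 6727 over the 3 ages, 9648 for 48h against 24h and 117 for 48h against 12h. Only the 6 libraries with scaling gave 6, 3809 and 19 for the 3 contrasts. Scaling with 12h replicate 2 left out gave 1890 over the 3 ages, 5001 for 24h against 12h and 1 for 48h against 12h. Only the 6 libraries with 12h replicate 2 left out gave 20 for 24h against 12h and 22 for 48h against 12h. Those calls, 2 with all libraries and both of the evening-phased list, were 0 with an estimated correlation and 0 with fry, which tests against no change. The added lists are not in these counts. For the morning-phased list, whose test was added, fry gave adjusted p-values of 0.0468, 0.0438 and 0.00407 for the contrasts in the order above. Camera on ranks gave that list an adjusted p of 0.00156 in each contrast. Except where fewer samples or genes were used by construction, the cause was not tested.

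The replicate block gave 81, 21, 4 and 102 genes, and 1703, 1228, 2879 and 98 without 12h replicate 2. Over all tested genes, most libraries with the same number did not deviate together: 1 of 9 pairs had a correlation over 0.1 (-0.0778 to 0.351), and 2 of 9 libraries correlated best with their own number. The 13 genes with at least 1 FPKM in each library numbered 3 and listed at 0 in the others are an exception.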

Other observations

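The tests of the patterns below and of other splits were chosen after the results they bear on had been seen, and the isoflavonoid and photoperiod lists after the planned lists had been. Isoflavonoids are flavonoids through which soybean roots signal to rhizobia. Of the 20 loci listed for their synthesis, 19 were tested and 0 passed in any contrast, over all genes or adjusted over the list alone. Glyma.01G228700 had 733 ± 148 FPKM at 12h, 721 ± 167 at 24h and 498 ± 45.8 at 48h, and Glyma.07G202300, published as an isoflavone synthase gene, had 150 ± 33.1, 258 ± 37.4 and 209 ± 50.5 FPKM (SD, n = 3 each). Camera called the list down for 48h against 12h (adjusted p = 0.000473; adjusted p = 0.317 with an estimated correlation) and for 48h against 24h (adjusted p = 0.0155; adjusted p = 0.446 with an estimated correlation), and did not call it for 24h against 12h (adjusted p = 0.718). For 48h against 12h the mean log2 fold change of the list was -0.076, with 13 of 19 members negative and 6 positive, beside a median of 0.341 over all tested genes, and against no change fry gave an adjusted p of 0.87; for 48h against 24h the mean was -0.097, with 12 negative and 7 positive, beside a median of 0.228 (fry adjusted p = 0.87). Of the 11 loci of the photoperiod list, which also holds further clock loci, 4 were tested and 0 passed over all genes. All 4 had a positive log2 fold change for 48h against 24h (mean 1.02). For 24h against 12h 3 were negative and 1 positive (mean -0.711), and for 48h against 12h 2 were positive and 2 negative. Adjusted over the list alone, 1 passed for 48h against 24h, Glyma.19G224200, with 0.304 ± 0.309 FPKM at 24h and 2.03 ± 0.592 FPKM at 48h (SD, n = 3 each).

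The library 12h replicate 2 stood apart from the other 12h libraries. After median-of-ratios scaling its root mean square log2 difference to the nearer of them was 1.08. The largest for any other pair of 1 group was 0.828, which argues against a library-wide scaling difference as the whole cause. Over the 2695 genes with a mean of at least 50 FPKM these values were 1.82 and 1.03. That mean included 12h replicate 2, so its own high values could bring genes in. The comparison therefore cannot decide on shallower sequencing, which stays open. A mislabelled 24h library stays open, because the values disagree: its root mean square log2 difference was 0.762 to 0.949 to the 24h libraries and 1.13 and 1.32 to the other 12h libraries, yet those and 24h replicate 1 also lay nearest to a 48h library, and all 4 morning-phased loci were lower in it than in every 24h library (3 after scaling), while at 3499 (92%) of the 3803 genes called for 24h against 12h without it, its value lay nearer the 24h mean. A further test, added after the first had counted against mislabelling, counted on which side it lay at the 50 genes with the largest fold changes. It gave 36 nearer 24h, against 39 and 11 for 12h replicates 1 and 3 and 22, 36 and 45 for 24h replicates 1, 2 and 3. These counts are not like for like, because 12h replicate 2 was left out of every fit together with the library judged. For 12h replicates 1 and 3 that left a single 12h library, and the genes could differ each time. The test therefore cannot place 12h replicate 2 and was set aside. A difference between the plants sampled was not tested.

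On the log2 scale, the morning-phased loci were lower and more variable at 24h than at 48h. In FPKM the SD was larger at 48h than at 24h, except for Glyma.07G048500 (4.55 at 24h and 4.32 at 48h). By the labelled ages these groups were sampled at the same hour of the day, if they were sown at the same hour, which was not checked. The mean log2 difference of the 4 loci was 2.30 as deposited and 2 after scaling, which argues against scaling alone; it was 3.01 without 24h replicate 1 and 1.64 without 24h replicate 2. Libraries of 1 age taken at different phases of the clock are a candidate explanation. It would make the morning and evening levels of libraries go opposite ways within groups, and over the 7 evening loci, with scaled values, r was -0.63 (exact permutation p = 0.269; rho -0.467, exact p = 0.319; r -0.292 without the 2 libraries farthest from the median). In all, 4 such correlations were computed, with deposited values (r -0.331, exact p = 0.579) and with 2 LUX loci picked after seeing values (r -0.848, exact p = 0.0556 scaled; r -0.744, exact p = 0.37 deposited, where rho alone had an exact p of 0.0231). Without the 2 farthest libraries these 3 r were 0.106, -0.301 and -0.19. None of the r passed, adjusted p-values were 0.222 to 0.579, and age and phase stay open.

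In the 3 libraries numbered 3, 13 genes had at least 1 FPKM in each and were listed at 0 in the other 6; the highest count for another of the 84 choices of 3 libraries was 5, and scanning such choices at several thresholds is how the pattern was found. With 0 of them within 10 positions of another in the order of the IDs, 1 stretch of the genome is argued against, and with 7 reaching 10 FPKM, up to 348 FPKM, so are chance misses of low genes. A shared library or processing batch may be behind it: the number of values above 0 and under a cutoff set these libraries apart at 6 of the 7 cutoffs tried (exact p 0.0119 to 0.0238, and 0.714 at 0.03 FPKM). These cutoffs are nested, the first look at them preceded the test, and the labels name no batch, so this stays open, as does a failed estimate in the other 6 libraries, which was not tested.

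Other splits of the libraries into groups of 3 were fitted in the same way. For the 3 ages, 14 of 100 splits drawn from 280, the real one included, gave at least the 9 genes of the real groups, and the highest other gave 7021, so chance is not excluded. For single contrasts there are 10 splits, too few for a share under 0.05. As many genes came from 2 of 10 for 24h against 12h (12, highest other 5061) and 1 of 10 for 48h against 12h (37, highest other 6). For 48h against 24h the real count of 0 fixed the outcome at 10 of 10 (highest other 5), which says nothing. With only the 6 libraries compared these were 3 of 10 (9, highest other 25), 1 of 10 (5412, highest other 5) and 1 of 10 (62, highest other 9). The split with 5061 genes is an exchange of 12h replicate 2 and 24h replicate 1, and that with 7021 also put 12h replicate 2 with 24h replicates 2 and 3, which points to a structure of the libraries other than the 3 ages. Those 3 libraries had the highest shares of the FPKM sum in their 100 highest genes (53.6%, 38.5% and 38.0%), and 23 genes were listed at 0 in them and at 1 FPKM or more in the other 6.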
